A study of Mus musculus with 8 samples.

How the data were processed

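RNA from primary cultured mouse keratinocytes harvested before confluence was sequenced in 8 libraries, 4 from wild-type (WT) mice and 4 from HOIL1 ΔRING1 (HdR) mice. Per the labels' protocols, total RNA was taken directly from the culture plates with the RNeasy mini kit, libraries were made with the NEBNext Ultra II RNA kit, and sequencing was on an Illumina platform. The genome build was GRCm38, per the submitters' processing notes. The labels do not state the aligner, the counting tool, the annotation, any filter, the strand setting, or whether the 4 libraries of a genotype came from separate animals or separate cultures. The p-values therefore measure only the spread between these libraries.

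The authors deposited 1 table with a row per gene symbol and a column per library, and its values are signal: coverage, the whole-number sum of aligned bases over each gene, not scaled for library depth or gene length. This unit was read from the values, since no header or label states it. The commonest non-zero value was 302, followed by 604 and 906, as if a full read pair added 2 reads of 151 bases. Of the non-zero values under 10 such steps, 16.9% were whole multiples of the step, so the values are not read counts. Division by 302 gives approximate read-pair equivalents. Because coverage is not a count of independent molecules, no count-based interval or detection floor is given. Longer genes gather more aligned bases, so levels compare a gene between libraries and not different genes. The table held 19457 genes, of which 1087 had no signal in any library. By symbol, 19163 matched GENCODE vM21 (GRCm38), the source of the coordinates, and 294 did not.

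The test planned before the data were examined was a model of read counts, and it was not used because the values are not counts. The fallback written beside it was used: limma on log2 values, with a pseudocount of 1 and genes with a mean of at least 1. The pseudocount shrinks the folds of genes with levels near 1. That fallback assumed normalised values, and the coverage sums had no depth scaling, so each library was first scaled with trimmed-mean (TMM) factors to aligned bases per megabase of its normalised total (written aligned bases per Mb). The TMM calculation trimmed 30% of log ratios and 5% of mean levels at each end. The fits used R 4.3.3 and limma 3.58.1 (lmFit and eBayes with a mean trend and robust variance, statmod 1.5.0), with genotype as the only factor and HdR minus WT as the direction. The test was two-sided with Benjamini-Hochberg adjustment over 11870 genes, and a gene was called at adjusted p under 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

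There were 33 gene lists fixed before the data were examined: 20 of keratinocyte, signalling and stress genes and 13 of markers for other cell types or RNA quality. The 23 lists with at least 5 tested genes were tested with limma's camera, preset correlation 0.01, and adjusted over the lists. Camera with an estimated correlation and fry, a self-contained test of whether a list's genes move one way on balance, were run beside it. The genes named in the text follow a rule fixed at the same time. It takes Rbck1, Rnf31 and Sharpin, and the 10 higher and 10 lower called genes with the largest log2 fold change. Those 20 need a mean of at least 2 and no overlap between the groups' values, and predicted genes (Gm and Rik symbols) are skipped. From each list it takes up to 4 members with the smallest p. Genes outside this rule are marked where they appear.

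The calculation was tested on simulated data. For a simulated HdR minus WT comparison of 11864 genes, 78% of genes changed 1.5-fold and 93% of genes changed 2-fold were recovered, and 7.57% of the 185 calls were false. In simulated lists, 0 of 50 unchanged lists were called. The simulated genes varied independently, so this check cannot show how correlation between genes of a list affects camera with its preset. It changed 100 genes at each fold, far fewer than were called in the data.

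Alternatives changed 1 choice at a time, except limma-voom, which changed the variance model, the sample weights and the unit together. They were median-of-ratios and upper-quartile scaling, no filter and a stricter filter (5 aligned bases per Mb in 4 libraries), limma-voom with sample quality weights on read-pair equivalents, the replicate number as a block, a test against a fold of 1.2, pseudocounts of 0.1 and 5, and each library left out in turn. Thinning to the smallest library, GC and length correction, library totals as the only scaling, and leaving out HdR 4 and WT 4 together were added after seeing the data. No library was left out of the main comparison.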

Results

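Gene expression was measured by RNA sequencing in primary mouse keratinocytes, the epithelial cells of the epidermis, cultured and harvested before confluence. There were 4 WT and 4 HdR libraries. HdR mice carry HOIL1 ΔRING1, a form of HOIL-1L without its first RING domain. HOIL-1L is encoded by Rbck1 and is a subunit of the linear ubiquitin chain assembly complex (LUBAC), with the catalytic subunit HOIP (Rnf31) and SHARPIN (Sharpin). The series title concerns linear ubiquitination in keratinocytes, TNF-α and NF-κB signalling and psoriatic inflammation, and the comparison asks which keratinocyte transcripts differ with the HOIL1 genotype.

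The WT libraries held 5.04, 4.78, 5.43 and 5.13 Gb of aligned bases (mean 5.09 ± 0.267, SD, n = 4), about 16.9 ± 0.883 M read-pair equivalents. The HdR libraries held 4.31, 3.6, 3.85 and 2.31 Gb (mean 3.52 ± 0.857, SD, n = 4), about 11.6 ± 2.84 M. Every HdR library was shallower than every WT library, a mean difference of 1.58 Gb (exact permutation test, two-sided p = 0.029, the smallest that 70 regroupings allow), so depth and genotype are confounded. TMM factors lay between 0.974 and 1.01, and the 10 highest genes took 9.35% to 10.2% of the aligned bases of a library. Correlations of log2 levels across genes, which are not independent replicates, were 0.9944 to 0.9967 within WT, 0.9952 to 0.9966 within HdR and 0.9816 to 0.9889 between them. Between pairs of libraries, chi-square per degree of freedom on read-pair equivalents was 4.75 to 9.85 within WT and 1.68 to 3.23 within HdR. Lower depth also lowers this measure. The fit assumes a common spread for both groups. Whether the smaller HdR spread reflects shared animals or cultures cannot be told from the labels. The first principal component held 67.1% of the variance and separated the genotypes. WT 4 lay nearest to HdR on it, at 11.3, against 17.8 to 20.3 for the other WT libraries and -19.3 to -15.5 for HdR.

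**Figure D1:**
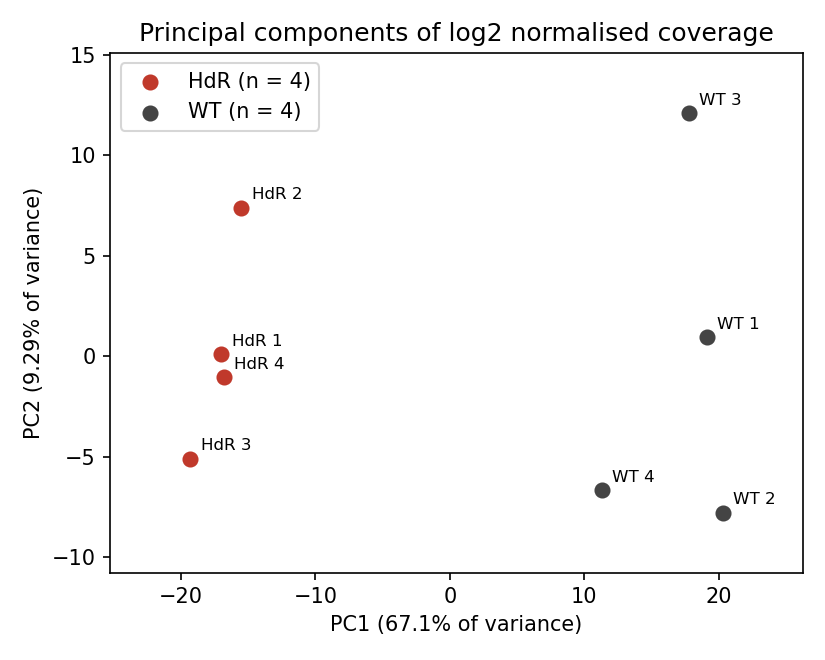
First and second principal components (arbitrary units, with the percent of variance on each axis) of log2 normalised coverage for the 4 WT and 4 HdR libraries, each point 1 library. The WT libraries lie between 11.3 and 20.3 on the first component and the HdR libraries between -19.3 and -15.5.

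Rbck1, the gene that carries the altered allele (GRCm38 chromosome 2, 152316334 to 152332653, minus strand), was lower in every HdR library. Its normalised coverage was 87.5 ± 3.4 aligned bases per megabase of library (per Mb) in WT and 43.7 ± 1.87 in HdR (SD, n = 4 each), a log2 fold change of -0.99 ± 0.047 (SE, limma adjusted p = 7.25e-11). Coverage is summed over the whole gene, so the deleted part and the rest cannot be told apart and the allele itself cannot be read from it. The transcripts of the other LUBAC subunits did not pass the test. Rnf31 (chromosome 14, 55591708 to 55603693) had 18.4 ± 0.922 in WT and 16.8 ± 1.64 in HdR, a log2 fold change of -0.13 ± 0.075 (adjusted p = 0.182). Sharpin (chromosome 15, 76347040 to 76351111) had 27.6 ± 1.07 and 25.6 ± 1.71, a log2 fold change of -0.11 ± 0.061 (adjusted p = 0.159).

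The WT and HdR libraries differed in many transcripts, mostly by small amounts. Of 11870 genes tested, 5346 (45%) were called by limma at adjusted p under 0.05, with 2517 higher and 2829 lower in HdR. The median absolute log2 fold change of the called genes was 0.29, and 184 differed more than 2-fold, 57 higher and 127 lower. In 4879 genes (41.1%) the values of the 2 genotypes did not overlap, where chance gives 2.86%. With upper-quartile scaling 3113 genes were higher and 2278 lower, so the balance of directions among small changes depends on the scaling (57.7% of calls higher, against 47.1%). Against a fold of 1.2, limma's treat test called 887 genes, 343 higher and 544 lower.

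The rule for naming genes took those with separated values and the largest log2 fold change at the pseudocount of 1. That pseudocount shrinks the folds of genes with levels near 1, so the order below depends on it: at 0.1 Kcnn4 was at 2.77 and Erdr1 at 2.72, and Fut1 at -3.50 and Saa3 at -3.01. Higher genes were Erdr1 (log2 fold change 2.57 ± 0.086, SE), the potassium channel gene Kcnn4 (2.32 ± 0.12), Wdfy1 (2.28 ± 0.10), the Bcl2-family gene Bcl2l15 (2.27 ± 0.23) and Mal (2.09 ± 0.11). Adam12, a metalloprotease, Tnfaip3, Fst, Csf3 and Wnt7a were at 1.88, 1.77, 1.75, 1.71 and 1.68. Erdr1 went from 6.6 ± 1.06 to 43.8 ± 2.84 aligned bases per Mb, and Fst, which encodes the activin antagonist follistatin, from 182 ± 33 to 605 ± 18.1 (SD, n = 4). Kcnn4 went from 1.99 ± 0.584 to 13.8 ± 1.13. Lower genes were Saa3 (-2.84 ± 0.13), Fut1 (-2.44 ± 0.16), Saa1 (-2.39 ± 0.23), Lcn2 (-2.20 ± 0.12), the gelatinase gene Mmp2 (-2.12 ± 0.13) and Krt10 (-2.05 ± 0.052). Stc2, Trib3, Egr1 and the glycine transporter gene Slc6a9 were at -2.0, -1.98, -1.79 and -1.76. Fut1 went from 8.28 ± 1.59 to 0.722 ± 0.366 aligned bases per Mb (SD, n = 4). All 20 had limma adjusted p of 0.000143 or lower. Trib3 (chromosome 2, 152337422 to 152344032) is a neighbour of Rbck1 and does not overlap it in the annotation. Erdr1 had no position in the annotation used, and Saa1 has a close paralogue with which reads could be shared.

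NF-κB target genes rose more often than they fell. Of 36 tested, 23 were higher in HdR, 7 lower and 6 not called, with a median log2 fold change of 0.279 (camera adjusted p = 5.8e-05, and adjusted p = 0.18 with an estimated correlation). Against a fold of 1.2, 13 were called higher and 3 lower. Tnfaip3, which encodes the NF-κB feedback inhibitor A20, rose from 30 ± 3.9 to 104 ± 8.06 aligned bases per Mb (SD, n = 4, chromosome 10, 19000910 to 19015657). Csf3, which encodes granulocyte colony-stimulating factor, rose from 0.776 ± 0.283 to 4.77 ± 0.248. The chemokine genes Ccl2 and Cxcl5 rose from 6.9 ± 0.942 to 19.5 ± 2.63 and from 5.75 ± 0.907 to 16.2 ± 1.5. The acute-phase gene Saa3 and the antimicrobial gene Lcn2, also on the list, fell from 48.5 ± 9.83 to 5.85 ± 0.542 and from 46.7 ± 8.22 to 9.26 ± 0.898.

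Genes of the TNF and NF-κB pathway itself were not called as a group. Of 28 tested, 5 were higher, 5 lower and 18 not called (camera adjusted p = 0.87). Tnf was higher, at 13.1 ± 2.26 against 5.95 ± 0.177 aligned bases per Mb (SD, n = 4, log2 fold change 1.01 ± 0.10, SE), as were Traf3 (0.36 ± 0.053) and Nfkb2 (0.19 ± 0.039), while the TNF receptor gene Tnfrsf1a was lower (-0.39 ± 0.041). Of 16 LUBAC and linear ubiquitin regulators, 3 were higher and 7 lower (camera adjusted p = 0.43), and 4 and 4 with upper-quartile scaling. Beside Rbck1 and Tnfaip3 these included Tnip3, which encodes an A20-binding protein, and the ubiquitin-binding adaptor gene Optn (-0.58 ± 0.074). Tnip3 was near the floor in WT, at 0.216 ± 0.0795 aligned bases per Mb against 1.87 ± 0.296 in HdR (SD, n = 4), so its log2 fold change of 1.24 ± 0.13 (SE) is set mainly by the pseudocount and was 2.66 with a pseudocount of 0.1.

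Psoriasis and IL-17 responsive epidermal genes were split. Of 26 tested, 9 were higher, 10 lower and 7 not called, and adjusted over the list alone 9 and 11 (camera adjusted p = 0.96). Cxcl5 and Il24 (0.47 ± 0.039) were higher, and Lcn2 and the IL-17 receptor subunit gene Il17rc (-0.49 ± 0.038) were lower. In antigen presentation, 9 of 16 genes were higher and 4 lower (median 0.185, camera adjusted p = 0.041, and adjusted p = 0.35 with an estimated correlation). B2m, the class I light chain gene, rose from 83.9 ± 3.32 to 130 ± 3.96 aligned bases per Mb (SD, n = 4), and the immunoproteasome gene Psmb8 from 5.56 ± 0.818 to 10.4 ± 1.2. This list's call was lost without WT 4 (adjusted p = 0.0597), HdR 1 (0.0703) or HdR 2 (0.0574), with upper-quartile scaling (0.057), with library totals only (0.0559), after thinning to the smallest library (0.057) and with the stricter filter (0.0789). Of 12 type I interferon response genes, 3 were higher and 2 lower (camera adjusted p = 0.56), with the RNA sensor gene Ddx58 at 0.36 ± 0.078. These counts rest on single libraries: 4 higher and 0 lower without WT 1, 4 and 1 without WT 2, 3 and 1 without WT 3 or HdR 4, 2 and 1 without WT 4 or HdR 1, and 1 and 1 without HdR 3. With upper-quartile scaling they were 3 and 1, and with the stricter filter 2 and 1.

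Among cell death genes, 13 of 29 were higher and 4 lower (median 0.147, camera adjusted p = 0.03, and adjusted p = 0.18 with an estimated correlation). Against a fold of 1.2, 0 were called higher and 2 lower, so the rise consists of small changes. Mlkl, the necroptosis effector gene, rose by 0.40 ± 0.050 and the death receptor gene Tnfrsf10b by 0.32 ± 0.045 on the log2 scale (SE). The anti-apoptotic gene Mcl1 (-0.30 ± 0.037) and the BH3-only gene Bbc3 (-0.64 ± 0.094) fell. Of 19 p53 targets, 8 were higher and 8 lower (camera adjusted p = 1), with Ccng1 at 0.51 ± 0.039 and Btg2 at -0.72 ± 0.052.

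Differentiation genes were lower in HdR, and none of the 41 tested was called higher, against 1 without WT 3 and 1 with limma-voom. Of these 41 genes of suprabasal keratinocytes and the cornified envelope, 28 were lower, 30 adjusted over the list alone, with a median of -0.737 (camera adjusted p = 1.7e-09, and adjusted p = 0.44 with an estimated correlation). The number lower ran from 21 without WT 1 to 35 without WT 4 when each library was left out. It was 19 with the replicate number as a block and 12 against a fold of 1.2. The suprabasal keratin genes Krt10 (chromosome 11, 99385254 to 99389364) and Krt1 fell from 208 ± 10 to 49.4 ± 3.67 and from 228 ± 19.3 to 86.1 ± 8.15 aligned bases per Mb (SD, n = 4). Notch3 and the Notch target Hes1 fell by 0.52 ± 0.049 and 0.41 ± 0.048 on the log2 scale (SE). WT 4, the WT library nearest to HdR, lay 0.54 of the way from the other WT libraries to the HdR mean in the score of this list.

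Basal keratinocyte and hemidesmosome genes were higher, 10 of 18 with 1 lower (median 0.128, camera adjusted p = 0.0093, and adjusted p = 0.45 with an estimated correlation). The integrin genes Itga3 and Itgb4 rose by 0.53 ± 0.042 and 0.43 ± 0.041, and the laminin gene Lamb3 by 0.37 ± 0.035 (log2, SE). The number lower was 0 without WT 1, HdR 3 or HdR 4 and with upper-quartile scaling, and 2 without WT 3. WT 4 lay 0.49 of the way to HdR in this list's score. Cell junction genes went both ways, with 5 of 25 higher and 9 lower (camera adjusted p = 0.43), and 8 and 9 with upper-quartile scaling. The desmosomal genes Pkp1, Jup and Perp (-0.35 ± 0.035, -0.26 ± 0.034 and -0.34 ± 0.040) and the gap junction gene Gjb2 (-0.33 ± 0.041) were among the lower ones.

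Cell cycle genes rose together. Of 24 mitosis genes 21 were higher and none lower, 22 adjusted over the list alone (median 0.299, camera adjusted p = 2e-08, and adjusted p = 0.27 with an estimated correlation). Of 23 DNA replication and S phase genes 18 were higher and none lower, 19 adjusted over the list alone (median 0.335, camera adjusted p = 1.4e-07, and adjusted p = 0.26 with an estimated correlation). Against a fold of 1.2, 5 mitosis genes and 6 S phase genes were called higher and 0 lower, so most of these rises were not shown to exceed that fold. The mitotic kinase gene Plk1 rose from 61.2 ± 6.48 to 92.4 ± 3.97 and the ribonucleotide reductase gene Rrm2 from 239 ± 16.5 to 364 ± 14.5 aligned bases per Mb (SD, n = 4). Kif20a and Mcm5 rose by 0.57 ± 0.049 and 0.47 ± 0.047 (log2, SE). WT 4 lay 0.40 of the way to HdR in the mitosis score and 0.26 in the S phase score.

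**Figure D2:**
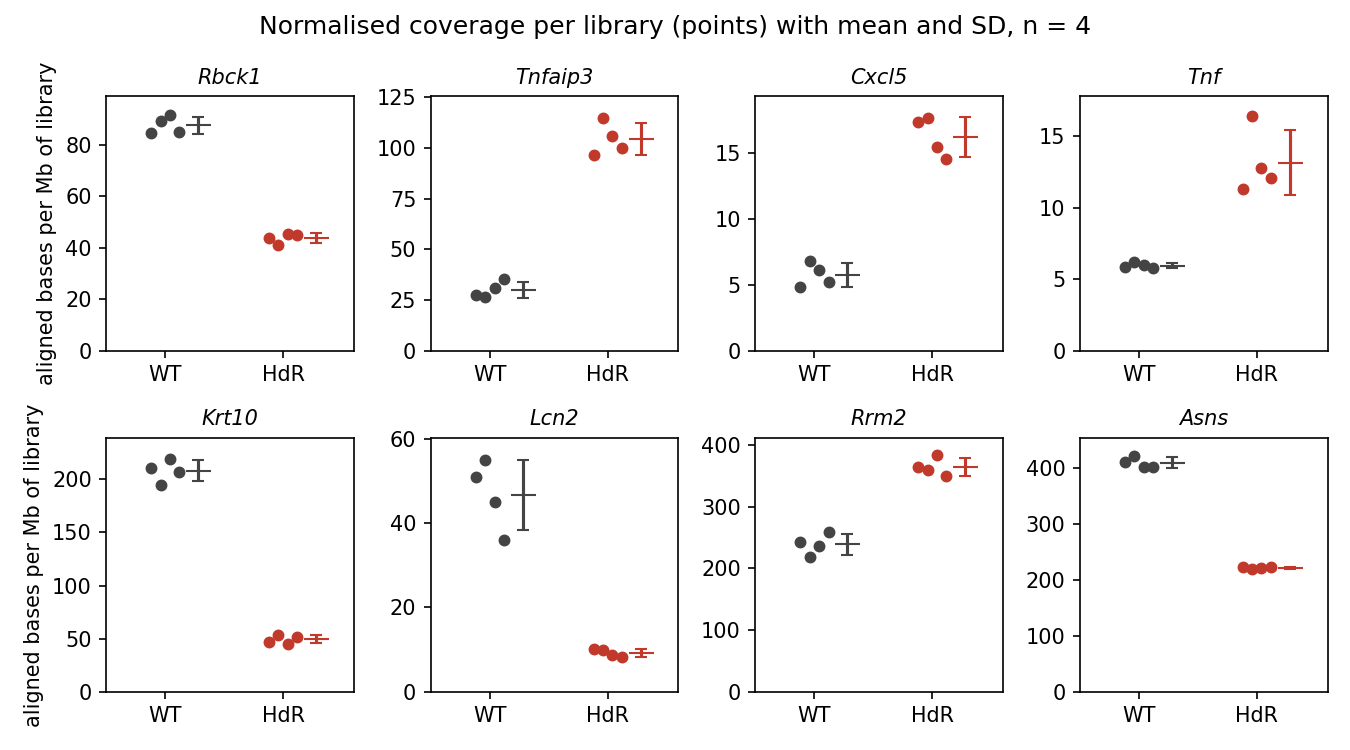
Normalised coverage (aligned bases per Mb, linear axis from 0) of 8 genes in the 4 WT and 4 HdR libraries, with points for libraries and bars for the mean and SD. The 2 genotypes do not overlap in any of the 8 genes, with Rbck1, Krt10, Lcn2 and Asns lower and Tnfaip3, Cxcl5, Tnf and Rrm2 higher in HdR.

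Wound and stress keratinocyte genes were split, with 9 of 22 higher and 9 lower (median -0.038, mean 0.099, camera direction higher, adjusted p = 0.55). Inhba, which encodes an activin subunit, rose from 97.5 ± 8.62 to 221 ± 5.64 aligned bases per Mb (SD, n = 4), and the EGF receptor ligand genes Ereg and Tgfa rose by 0.89 ± 0.084 and 0.53 ± 0.042 (log2, SE). Stfa3, a member of a family of close copies, was at -0.81 ± 0.077. In the matrix and mesenchymal transition list, 8 of 18 were higher and 5 lower (camera adjusted p = 0.49). Cyr61 and the gelatinase gene Mmp9 rose by 0.70 ± 0.037 and 1.08 ± 0.12, while Mmp2 and Timp3 (-0.72 ± 0.062) fell. Of 21 cholesterol synthesis genes 3 were higher and 3 lower (camera adjusted p = 0.78), but 3 and 6 without WT 2, and 5 and 2 with upper-quartile scaling.

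Several stress and metabolic programmes were lower. Of 19 unfolded protein and integrated stress response genes, 13 were lower and 4 higher (median -0.335, camera adjusted p = 0.00057, and adjusted p = 0.18 with an estimated correlation). The asparagine synthetase gene Asns fell from 409 ± 9.43 to 222 ± 1.11 aligned bases per Mb, the serine synthesis gene Psat1 from 433 ± 29.7 to 229 ± 3.79, and the glutathione-degrading enzyme gene Chac1 from 28.7 ± 2.28 to 9.54 ± 0.598 (SD, n = 4). Of 21 hypoxia and glycolysis genes, 13 were lower and 2 higher (median -0.174, camera adjusted p = 0.00052, and adjusted p = 0.18 with an estimated correlation). Egln3, a HIF prolyl hydroxylase gene, fell from 179 ± 5.82 to 82.9 ± 6.13 and the mitophagy gene Bnip3 from 74.2 ± 4.72 to 33.7 ± 2.03. Of 20 Nrf2 and oxidative stress genes, 11 were lower and 3 higher (median -0.177, camera adjusted p = 0.026, and adjusted p = 0.45 with an estimated correlation), with Osgin1 at -0.44 ± 0.049 and Aldh3a1 at -0.96 ± 0.11 (log2, SE). Without WT 3 the hypoxia list had 4 higher and 12 lower, and with upper-quartile scaling 4 and 11. WT 4 lay 0.17, 0.05 and 0.52 of the way to HdR in the scores of these 3 lists.

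Immediate early genes fell, with 16 of 20 lower and 1 higher (median -0.448, camera adjusted p = 3.8e-06, and adjusted p = 0.24 with an estimated correlation). Junb fell from 1094 ± 56.5 to 722 ± 18 and the phosphatase gene Dusp1 from 187 ± 7.49 to 117 ± 3.5 aligned bases per Mb (SD, n = 4). The number called higher was 0 without WT 1, WT 3, HdR 2 or HdR 3, 2 without WT 4, and 3 with upper-quartile scaling. Egr1 fell from 215 ± 44 to 60.5 ± 5.52 and Ier2 from 264 ± 17.1 to 161 ± 7.68.

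**Figure D3:**
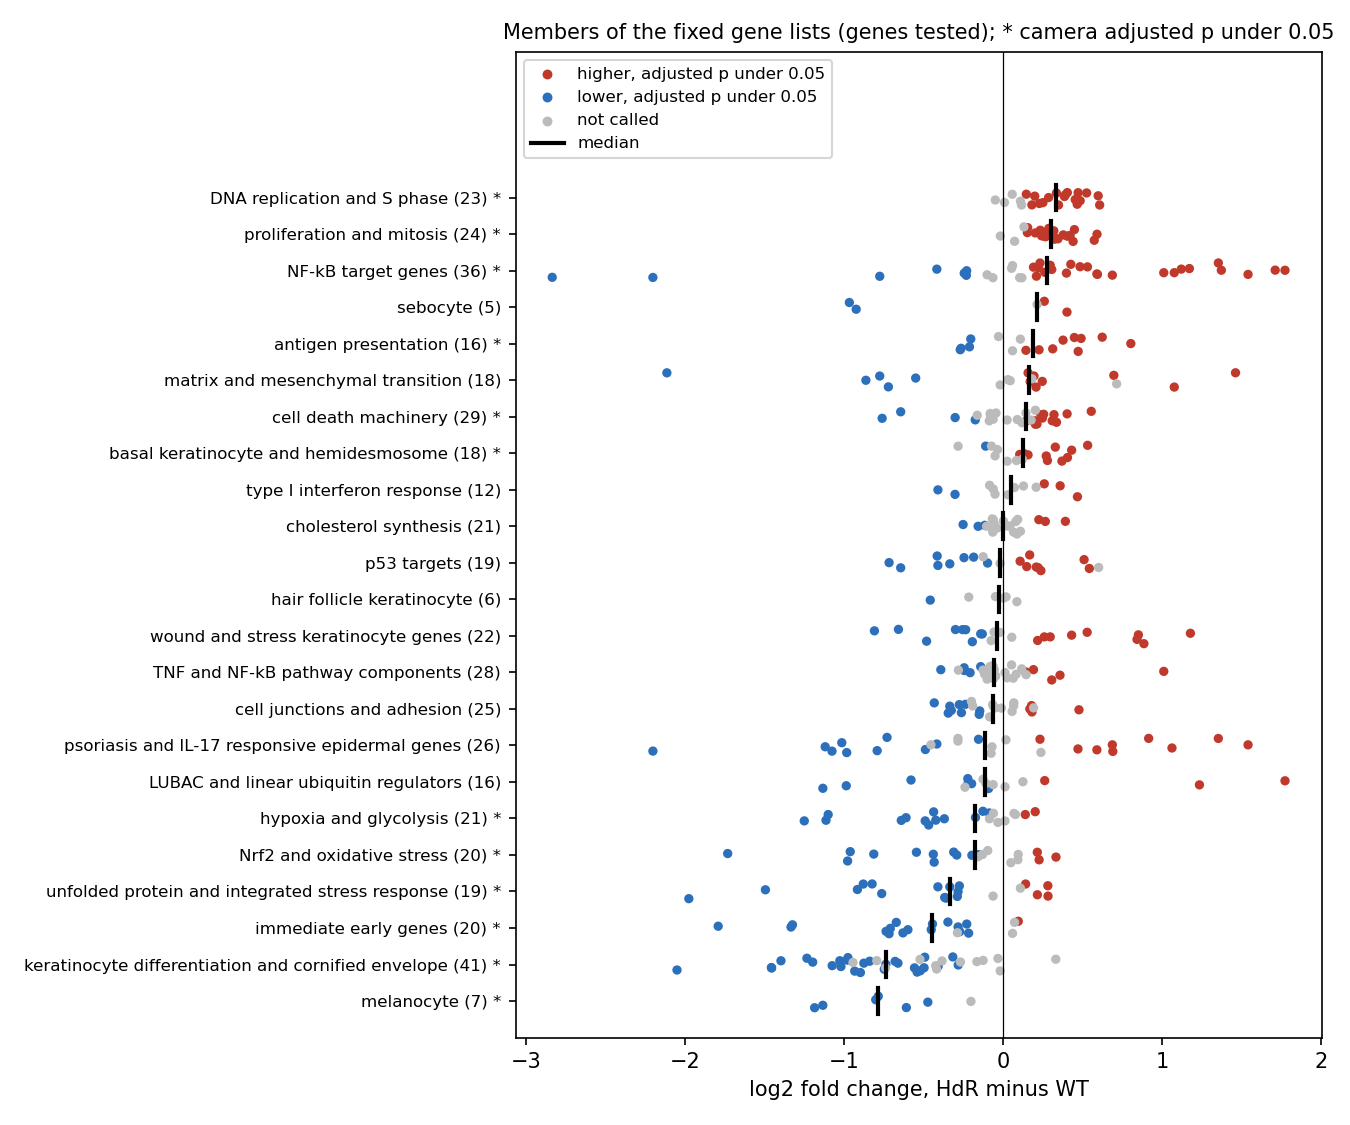
Log2 fold change (HdR minus WT, n = 4 each) of every tested member of the 23 tested lists, with 1 point per gene, colour for limma calls, a bar for the median, and an asterisk for camera adjusted p under 0.05. The differentiation (median -0.737) and melanocyte (median -0.785) lists lie lowest and the S phase (median 0.335) and mitosis (median 0.299) lists highest.

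Most marker genes of other cell types did not reach the filter, but 7 of 10 melanocyte and 5 of 8 sebocyte markers with a row did. Of 7 tested melanocyte genes, 6 were lower and none higher in HdR (median -0.785, camera adjusted p = 5.8e-05, and adjusted p = 0.18 with an estimated correlation). The pigment enzyme gene Dct fell from 16.4 ± 1.53 to 6.66 ± 0.94 and the melanosome gene Pmel from 9.74 ± 0.906 to 3.88 ± 0.128 aligned bases per Mb (SD, n = 4). This fall went in the same direction as the differentiation, stress, hypoxia, Nrf2 and immediate early lists. These values cannot tell fewer melanocytes in the HdR cultures from lower levels within cells. Of 6 hair follicle genes none was higher and 1 lower, none adjusted over the list alone (camera adjusted p = 0.78). The lower gene, the companion layer keratin gene Krt75 (-0.46 ± 0.15), lost its call without WT 1, WT 2, HdR 1, HdR 3 or HdR 4 (adjusted p 0.0683 to 0.0909) and with upper-quartile scaling (0.0568). The Krt75 call was also lost after thinning to the smallest library (limma adjusted p = 0.0791) and with GC and length correction (0.0509). Of 5 sebocyte genes 2 were higher and 2 lower (median 0.214, mean -0.203, camera direction higher, adjusted p = 0.8), with the lipid synthesis gene Fasn at 0.40 ± 0.043 and Mgst1 at -0.92 ± 0.084.

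The other marker lists had fewer than 5 tested genes and were not tested as lists. Of 2 fibroblast genes 1 was lower, and 2 adjusted over the list alone. Fbln1 had 36 ± 1.44 in WT and 32.7 ± 1.56 in HdR (SD, n = 4, limma adjusted p = 0.0529). It was called lower without WT 3 (adjusted p = 0.0287) or HdR 4 (0.046), with limma-voom (0.0257) and with the stricter filter (0.0493). Of the macrophage and Langerhans cell markers only Epcam, an epithelial adhesion gene, was tested, and it rose by 0.44 ± 0.057 (log2, SE). Of 2 mast cell and neutrophil genes both fell, Cxcr2 (-0.74 ± 0.12) and S100a8 (-1.01 ± 0.14), the latter also an epidermal gene. Of 2 endothelial genes 1 was higher (Flt1, 0.47 ± 0.11), and of 4 muscle genes 3 were higher, among them Tagln (0.51 ± 0.089) and Acta2 (0.15 ± 0.035). The tested T cell marker, Thy1, which fibroblasts share, was lower (-0.39 ± 0.13), a call lost without WT 1, WT 2, HdR 2 or HdR 4 (adjusted p = 0.0952, 0.0733, 0.0582 and 0.0617). The Thy1 call was also lost after thinning to the smallest library (log2 fold change -0.24, limma adjusted p = 0.326) and with no filter (0.0528). The tested adipocyte marker Lpl was lower (-0.37 ± 0.10), the Schwann cell marker Mbp was not called (0.03 ± 0.045), and none of the erythroid genes reached the filter. Of 4 tested RNA quality genes 2 were lower and none higher. Hist1h1c was at -0.38 ± 0.10 and Lars2 at -0.79 ± 0.23, and the Lars2 call was lost without any single HdR library (adjusted p 0.0573 to 0.0725). Neat1 and Malat1 were not called (0.12 ± 0.052 and 0.17 ± 0.093). Neat1 was called higher without WT 3 (adjusted p = 0.0346) or HdR 2 (0.019), with upper-quartile scaling (0.0202) and with limma-voom (0.0365), and Malat1 without WT 2 (0.0362). Neat1 was also called higher after thinning to the smallest library (limma adjusted p = 0.0445) and with library totals only (0.0378).

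Except where another count is given, the numbers of called list members adjusted over the list alone equalled those over all genes. None of the 12 lists called by camera was called with an estimated correlation. Every HdR library was shallower than every WT library, and the labels give no batch, day or animal by which the comparison could be divided.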

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

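The tests of the WT 4 library, YAP targets, depth, chromosome position and substrain were chosen only after the result was seen. The count over other splits and the relation of differentiation to cell cycle scores were written before.

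Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many changed genes. The real split gave 5346 genes and the highest of the others 2. Every other split mixes the genotypes within its groups, which widens their spread and lowers the count. The result speaks against chance only if the 8 libraries are independent. The labels do not say whether they are separate animals or cultures, so chance differences between animals or dishes are not excluded.

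Among 292 groups of 4 values (named genes, list scores and total aligned bases), 15 had a library far from the other 3 by Dixon's criterion (0.829 of the range), and 15 would be by chance. By library, 6 of the 15 were in WT 4. In aligned bases per Mb, WT 4 was high in Erdr1 (8.17, others 5.87 to 6.21), H2-Q4 (21.4, next 17.6), Itga3 (667, next 597), Lamb3 (572, next 533) and Acta2 (268, next 256). Its mitosis score was 6.25 on the log2 scale, against 6.11 to 6.12. HdR 2 was high in Erdr1 (48, next 42.6) and low in Parp14 (7.69, next 8.79). WT 3 was high in Tnip3 (0.335, next 0.18) and low in Ereg (13.8, next 18). HdR 4, the shallowest library, was high in Tyr (0.714, next 0.616) and low in Lpl (5.11, next 7.03). HdR 3 was low in S100a8 (400, next 513) and in the interferon score (2.93, next 2.95). WT 1 was high in Lars2 (256, next 143).

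WT 4 lay toward HdR on the first principal component (11.3, other WT 17.8 to 20.3). Against a mislabelled or swapped HdR library, over genes past 2-fold WT 4 lay a median of 0.223 of the way from the other WT libraries to HdR, and Rbck1 and Krt10 stood at 0.078 and 0.01. Against a single share of HdR RNA or reads, the genes lower in HdR stood at 0.347 of the way and the higher ones at 0.091, a difference of 0.256, where the other WT libraries had -0.021 to 0.036. In the scores of the 12 lists called by camera, WT 4 lay 0.54 of the way in differentiation, 0.52 in Nrf2, 0.49 in basal genes, 0.4 in mitosis, 0.26 in S phase, 0.24 in immediate early genes, 0.17 in the stress response, 0.14 in melanocyte genes, 0.05 in hypoxia, -0.04 in NF-κB targets, -0.28 in cell death and -0.33 in antigen presentation. The source of the shift stays open, and no biological explanation was tested.

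Differentiation, stress, hypoxia and immediate early genes were lower and cell cycle genes higher in HdR. Against depth, 111 of the 115 called members of these 6 lists kept their call and direction after thinning to the smallest library. A difference in culture density or growth state at harvest may account for the pattern. Within genotypes the differentiation and mitosis scores had Pearson r = -0.77 (exact permutation p = 0.071) and Spearman rho = -0.6 (p = 0.21) over 8 libraries. Without WT 4 and HdR 3, deviations from the unchanged 4-library group means gave Pearson r = -0.03, so the relation rests on those 2. The group means were not recalculated for that value. Lower density would raise YAP targets, and 10 of 22 were higher and 5 lower (camera p = 0.024, and p = 0.31 with an estimated correlation), which does not decide it. Growth state and an effect of the genotype cannot be told apart, since the labels record no density at harvest and no shared culture date.

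Erdr1, Wdfy1 and Nnt (8.49 ± 1.16 in WT, 17.7 ± 1.58 in HdR, SD, n = 4, log2 fold change 0.98 ± 0.092, SE; chosen after its values were seen) separated the genotypes. That 24 of 24 values lay on their own group's side was fixed by the choice of these genes and tests nothing. Against a segment carried along with the Rbck1 allele, 0 of the genes with a position lie within 5 Mb of it: Wdfy1 is on chromosome 1 and Nnt on chromosome 13. Within 5 Mb of Rbck1, 40.9% of 93 genes were called against 45.2% elsewhere (Fisher's exact p = 0.46, odds ratio 0.837, 95% interval 0.537 to 1.29). With so many calls elsewhere, this share cannot show whether a few genes near Rbck1 were affected. Trib3, its neighbour, was at -1.98. A different substrain background is a candidate explanation, as C57BL/6 substrains differ in Nnt, but no value here tests it and the labels give no substrain, so it and a genotype effect cannot be told apart.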

How the results depend on the processing

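Thinning, GC and length correction, library totals, leaving out HdR 4 and WT 4 together, and upper-quartile scaling for lists were chosen after seeing the data. The number of changed genes was 5346, and 4515 (thinned) to 5786 (limma-voom with sample weights, which changes several choices at once) under the alternatives, with 4561 to 5289 when each library was left out (2145 to 2477 higher, 2416 to 2812 lower). The exception was the test against a fold of 1.2, with 887 genes, 343 higher and 544 lower, which by construction leaves out small changes. Thinning gave 1 main call with the opposite sign and GC and length correction 8, the other settings 0. The median log2 fold change of all genes lay within 0.027 of 0 under each setting.

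For 122 named genes, 2464 of 2543 alternative values kept direction and call, 66 lost the call, 13 gained it and 0 reversed. Camera called 12 lists, fry 15, and camera with an estimated correlation 0, with adjusted p from 0.18 to 0.45 for the 12, because that test allows for genes of a list varying together. The 3 lists called by fry alone were LUBAC regulators (lower, fry adjusted p = 0.011), wound and stress genes (higher, 0.002) and cell junctions (lower, 0.0023). Antigen presentation, the list whose call was lost most often, had adjusted p from 0.0559 to 0.0789 where camera's preset lost it.

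The replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at 0.028, -0.068, -0.22 and 0.02, and 0 of 4 matched their own number best. With the replicate number as a block 4755 genes (2236 higher, 2519 lower) and 12 lists were called. Among named genes Krt75 lost its call and Neat1 and Malat1 gained one, and no other named call changed. Among all tested differentiation genes, named or not, 19 were called lower with the block, against 28 without it. The planned count models were not run, as the values are not counts. After thinning to the depth of HdR 4, with the tested genes in 3 equal groups by mean level, 69% of the calls in the lowest group kept call and direction, 79.7% in the middle and 89.3% in the highest.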

Other observations

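The test of amino acid genes and the scan along chromosomes were chosen after the values were seen. Genes for amino acid supply and tRNA charging fell together in HdR. Their list was not among those fixed beforehand. It leaves out members of the stress response list but shares Slc7a11 with the Nrf2 list. Of 29 tested, 27 were lower and none higher, with a median log2 fold change of -0.5. Psph and Mthfd2, of serine synthesis and mitochondrial folate metabolism, stood at -1.11 ± 0.049 and -0.94 ± 0.045 (SE), and the amino acid transporter genes Slc7a3, Slc7a11 and Slc7a5 at -1.71 ± 0.093, -1.73 ± 0.19 and -0.82 ± 0.067. The tRNA synthetase genes Aars and Nars stood at -0.62 ± 0.035 and -0.61 ± 0.039. These genes were named after their values were seen.

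Many of them are targets of ATF4, the transcription factor of the amino acid response. A lower amino acid response in HdR cultures may link this list with Asns, Chac1 and Trib3. Trib3 is also a neighbour of Rbck1, and a local effect of the allele on it was not tested. The camera test of the list gave p = 1.2e-16, and p = 0.026 with an estimated correlation. The list was put together after the values were seen and holds Slc6a9, so these p-values describe the pattern and are no independent evidence for it. Whether it follows from the genotype or from nutrient supply in the dishes was not tested.

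Genes past 2-fold clustered at 1 place. On chromosome 3 between 90 and 95 Mb (GRCm38), the epidermal differentiation complex, 13 of 86 genes were past 2-fold, where the share over all genes was 1.54% (adjusted p = 4.3e-07 over 516 windows, permutation p = 1e-04, the smallest 10000 permutations can give). Of these, 9 were lower, among them S100a8, S100a9, Hrnr and Sprr2b (-1.01, -1.08, -1.46 and -1.70), and 4 higher. The higher ones were Lce3a (1.32 ± 0.26), Lce3b (1.43 ± 0.28), S100a7a (1.06 ± 0.094) and Sprr2k (1.19 ± 0.15), with WT means of 3.21, 5.97, 4.03 and 1.13 aligned bases per Mb. Sprr2a1 and Sprr2a2 held identical values in all 8 libraries and count as 2 of the 9. Both p-values treat genes as independent, but many of the 13 belong to shared families (Sprr2, Lce3 and S100a), so they overstate the evidence. Hrnr, Rptn, Sprr2a1, S100a8, S100a9 and S100a7a were also members of the differentiation or psoriasis lists, so the cluster is not a separate result. The genes were named after their values were seen.

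Identical values in all 8 libraries occurred in 15 tested genes, in 7 sets, of which 6 genes were called. They include Snrpn with Snurf and Ugt1a5 with Ugt1a9, pairs that share a locus. No gene named by the rule was among them.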
